A study of Homo sapiens with 3 samples.

How the data were processed

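Total RNA of transduced HT29 cells was converted to biotin-labelled cRNA for Affymetrix arrays, per the labels' protocols, with 1 array for the vector and 2 for miR-146a. The deposited table gives 54675 probe sets on a log2 scale for each of 3 arrays, and the values were made by RMA per the submitters' processing notes, that is by background correction, normalization between arrays and a median-polish summary of the probes of each set. The version of RMA, and whether the 3 arrays were processed alone or with others, are not given in the sources used here. The authors' log2 values ran from 1.95 to 14.60, and the quantiles of the 3 arrays nearly coincided. No detection calls came with them, so signal over background was judged from the values only.

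Arrays were grouped by the transduction named in the labels: 1 array with the empty vector and 2 with the miR-146a construct. The replicate numbers of the miR-146a arrays come from their titles. No array was left out, and the 2 replicates did not hold identical files, since 19.3% of their probe sets were exactly equal (tolerance 0) and the rest differed. Probe sets were named through the platform annotation supplied with the data: 41091 of the 54613 non-control probe sets were paired with 1 gene, 1801 with several and 11721 with none here. Of those with 1 gene, 41037 matched a current gene by Entrez number in the RefSeq gene table given (no coordinates were used). Probe sets with several genes or none were not named. Some members of the lists had no probe set of their own under these rules and were not analysed here.

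For each gene the probe set with the highest average signal (the mean of both group means) was used, and genes were kept when this was above the median of all non-control probe sets, 5.13, which left 12444 of 19775 genes. Differences are miR-146a mean minus vector on the log2 scale, and folds are 2 to that power. SDs are of the 2 miR-146a arrays. The main test was limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 residual degree of freedom the spread comes from the miR-146a arrays alone, and the vector array is assumed to vary like them. Counts by size required a difference of at least 1 on the log2 scale in both miR-146a arrays.

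Before the data were examined, 30 gene lists, the naming rule, the tests and most alternatives were fixed. The lists covered reported miR-146a targets, immune, signalling, differentiation, stress and metabolic programmes, reference genes and markers of other cells, and some genes belong to more than 1 list. For each list the median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins; as genes are not replicates, the percentile describes these arrays only. In a family of 30 lists, 9 lay outside the central 95%. Camera, from limma, was run with a preset correlation of 0.01 and with an estimated one, which rests on 1 residual degree of freedom. With so few degrees of freedom the estimated setting called no list. A call lost there therefore cannot decide for or against a list. The genes named, with genes past the limma threshold to come first, are the 12 highest and 12 lowest by the smaller of their 2 array differences, up to 4 members of each list by the same measure, and the reported targets IRAK1, TRAF6, IRAK2, NUMB, SMAD4, EGFR and CXCR4; a further reported target is not reported here. Some further list members (VEGFA, LDHA, PFKFB3, AXIN2, LGR5, SOD2, NQO1, GCLC, CDH1, ISG20 and GBP2) were chosen after their values were seen, as were TXNIP and ARRDC4.

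Alternatives were the mean of all of a gene's probe sets (those below the filter included), every probe set separately, no filter or a filter at percentile 70, an intensity trend in the prior, cyclic loess or quantile normalization on top of the deposited values, and leaving out either miR-146a array. After the data were examined, 3 more were added: a variance prior from genes whose replicate values differ, a test of those genes alone, and a robust prior. The planned comparison of genes with miR-146a seed sites in their 3′ UTRs was not run, since no transcript sequences were used here.

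The fit was tested on simulated data made from the 12444 gene means and the differences between the miR-146a arrays, with 200 genes changed. With no ties imposed, limma recovered 87% of genes changed by 1 and 6% of those changed by 0.5 on the log2 scale, with 1 false call. With ties placed on the genes tied in the data it recovered 0% of either. With the prior from unequal replicates it then recovered 97% and 50%, with 6 false calls among 153. Without imposed ties this prior recovered 99% and 57%, with 4 false calls among 160. The simulated vector array was given the spread of the miR-146a arrays, so the few false calls cannot vouch for calls against a separately transduced culture. Figures were drawn with matplotlib 3.10.9.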

Results

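Gene expression was measured in HT29 cells, an established line from a human colorectal adenocarcinoma, after lentiviral transduction with a construct for miR-146a or with an empty vector. miR-146a is a microRNA known for dampening Toll-like and interleukin-1 receptor signalling through the adaptors IRAK1 and TRAF6. The series holds 3 arrays, with 1 of the empty vector and 2 labelled as replicates of the miR-146a cells, and its only comparison asks which transcripts differ between them. All 3 arrays cover the same 54613 probe sets besides controls, and their median log2 values were 5.14 (vector), 5.14 (miR-146a replicate 1) and 5.13 (miR-146a replicate 2). Of the 19775 genes with a probe set of their own, 12444 lay above the filter on low signal. Over these genes the difference between the 2 miR-146a arrays had an SD of 0.11, against 0.20 and 0.19 for replicates 1 and 2 against the vector. The number of arrays limits the precision of every value below. The labels do not say whether the 2 miR-146a replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical, and the vector array has no replicate of its own.

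The miR-146a locus is represented by 2 probe sets annotated to MIR146A, both below the filter of 5.13. One of them read 4.82 in the vector array and 5.03 and 5.23 in the miR-146a arrays. The other read 2.96 in the vector array and 2.79 and 2.82 in the miR-146a arrays. These probe sets read the host transcript and not the mature microRNA, and whether the construct carries their sequence is not given in the sources used here, so they do not check the labels.

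Interferon-stimulated genes were the group that differed most between the 2 conditions. Of the 35 measured members of this list, 32 were higher than the vector in both miR-146a arrays and 10 were at least 2-fold higher in both. IFITM1, a membrane protein that restricts virus entry, had a log2 value of 9.46 ± 0.02 (SD, n = 2) in the miR-146a arrays and 7.30 in the vector array, a 4.46-fold difference. IFI44L was 3.25-fold higher (6.90 ± 0.04, SD, n = 2, against 5.20), BST2, a protein that tethers budding virus to the cell surface, was 2.81-fold higher (8.45 ± 0.09, SD, n = 2, against 6.96), and MX1, an antiviral GTPase, was 2.80-fold higher (8.80 ± 0.11, SD, n = 2, against 7.31). ISG20 and GBP2 were the 2 members lower in both arrays, with mean log2 differences of -0.32 and -0.28.

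The list's median log2 difference was 0.62 (0.60 in replicate 1 and 0.61 in replicate 2), above all 10000 random lists matched on mean expression, whose central 95% ran from -0.02 to 0.09. No member passed limma at an adjusted p of 0.05 over all genes, and 26 passed when adjusted over the list alone, all of them higher. With the variance prior taken from genes whose replicate values differ, a setting chosen after seeing the data, 26 passed over all genes, again all higher, and adjusted over the list alone 31 passed as higher and 2 as lower. Camera with a preset correlation called the list higher (adjusted p = 4.2e-10), and that call was lost (adjusted p = 0.83 with an estimated correlation). In the same arrays the 5′ control probe sets of ACTB and GAPDH read lower than in the vector, by -0.18 to -0.32 on the log2 scale.

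**Figure D1:**
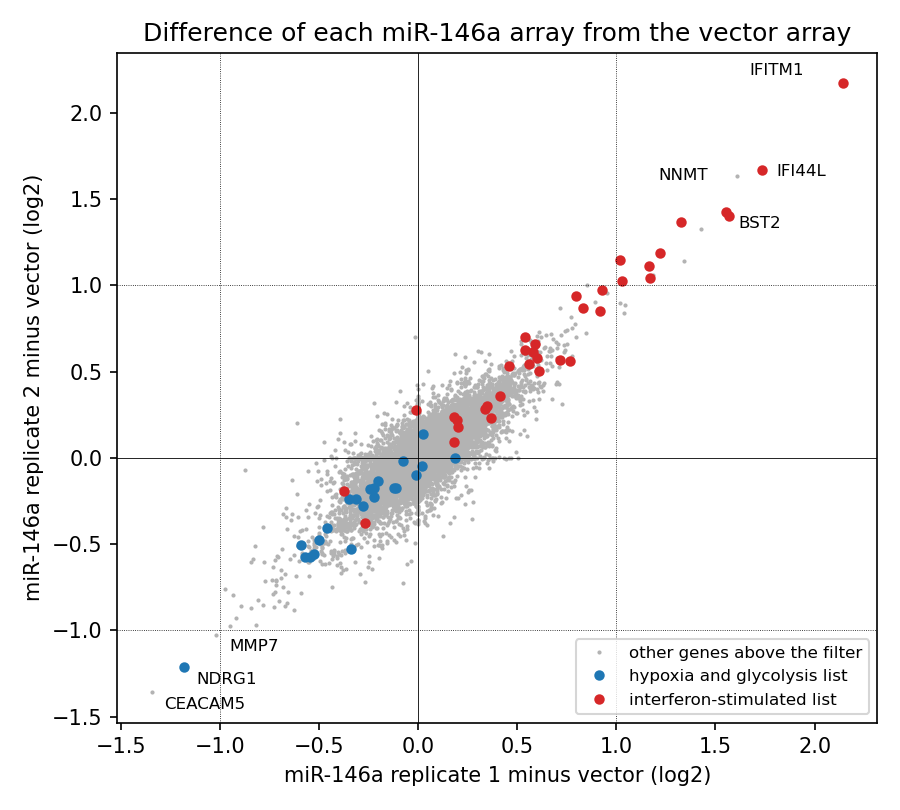
Log2 difference of miR-146a replicate 1 (x axis) and replicate 2 (y axis) from the vector array for each of the 12444 genes above the filter, with the interferon-stimulated list in red, the hypoxia and glycolysis list in blue and dotted lines at a 2-fold difference. Both axes share the same vector array, so both carry its chance deviation. Of the 15 genes at least 2-fold higher in both, 10 belong to the interferon-stimulated list.

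The 12 genes with the highest values relative to the vector were IFITM1, IFI44L, NNMT, BST2, MX1, CMPK2, IFITM3, PARP9, PSMB9, IFI27, UBE2L6 and IFITM2, with mean fold differences between 2.15 and 4.46. Of these, 8 belong to the interferon-stimulated list. Of the 15 genes at least 2-fold higher in both arrays 10 belong to it, against 0.042 expected by chance. NNMT, nicotinamide N-methyltransferase, was 3.08-fold higher and had a second probe set above the filter with a log2 difference of 1.65, though all its probe sets averaged gave 1.04. FOSB, an immediate early transcription factor, was 2.03-fold higher. PSMB9, a subunit of the immunoproteasome, was 2.37-fold higher, and UBE2L6, the conjugating enzyme for ISG15, was 2.18-fold higher. IFITM1, IFITM2 and IFITM3 are close paralogs whose probe sets can share signal, so the 3 values are not independent.

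The 12 genes with the lowest values were CEACAM5, NDRG1, MMP7, CEACAM6, TM4SF4, AHNAK2, CAV1, MICOS10P1, DDIT4, COXFA4L2, CLU and KLF9, with mean fold differences between 1.76 and 2.55. CEACAM5, the carcinoembryonic antigen, had a log2 value of 7.15 ± 0.01 (SD, n = 2) against 8.50 in the vector, a 2.55-fold difference, but its other probe set above the filter differed by 0.00 and the average of both by -0.68. CEACAM6, a close paralog of CEACAM5, was 1.95-fold lower, and its other probe set was lower by -1.20 on the log2 scale. NDRG1, a hypoxia-responsive gene, was 2.29-fold lower (9.47 ± 0.02, SD, n = 2, against 10.67). MMP7, a matrix metalloproteinase and Wnt target, was 2.03-fold lower (10.55 ± 0.00, SD, n = 2, against 11.58). CAV1, the coat protein of caveolae, was 1.81-fold lower with its other probe set at -0.52, and DDIT4, a stress-induced inhibitor of mTORC1, was 1.76-fold lower. With all probe sets averaged, those below the filter included, CLU and KLF9 each differed by -0.43 on the log2 scale, against -0.82 and -0.87. Above the filter, the other probe set of CLU was at -0.87, and those of KLF9 ranged from -0.79 to -0.09.

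As specified beforehand, limma called 0 genes higher and 0 lower among 12444, with a smallest adjusted p of 0.118, while 2933 genes had an unadjusted p under 0.05, 1813 of them higher and 1120 lower. The 2 miR-146a arrays held exactly equal values (tolerance 0) for 1610 of the 12444 genes. Such genes had very small standard errors in limma, as for ENG at 0.0075, against 0.0855 with the prior from unequal replicates. The counts that passed adjusted over a list alone, above and below, therefore favour genes with equal or nearly equal replicates. Limma's prior degrees of freedom were 0.55. With the prior from genes whose replicates differ they were 10.3, and 592 genes were higher and 294 lower at an adjusted p of 0.05, all 24 genes above included. That test takes the spread of the single vector array to be that of the miR-146a replicates. By size alone, 15 genes were at least 2-fold higher and 3 at least 2-fold lower in both arrays, and no gene was 2-fold apart between the 2 miR-146a arrays. In 100 simulated sets of unchanged arrays sharing 1 vector array, at most 0 genes were 2-fold apart in both and at most 2 were 1.5-fold apart in both, where 18 and 105 were observed, but the simulated spread is that of the 2 miR-146a arrays, which may be technical, and leaves out differences between separately transduced cultures.

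**Figure D2:**
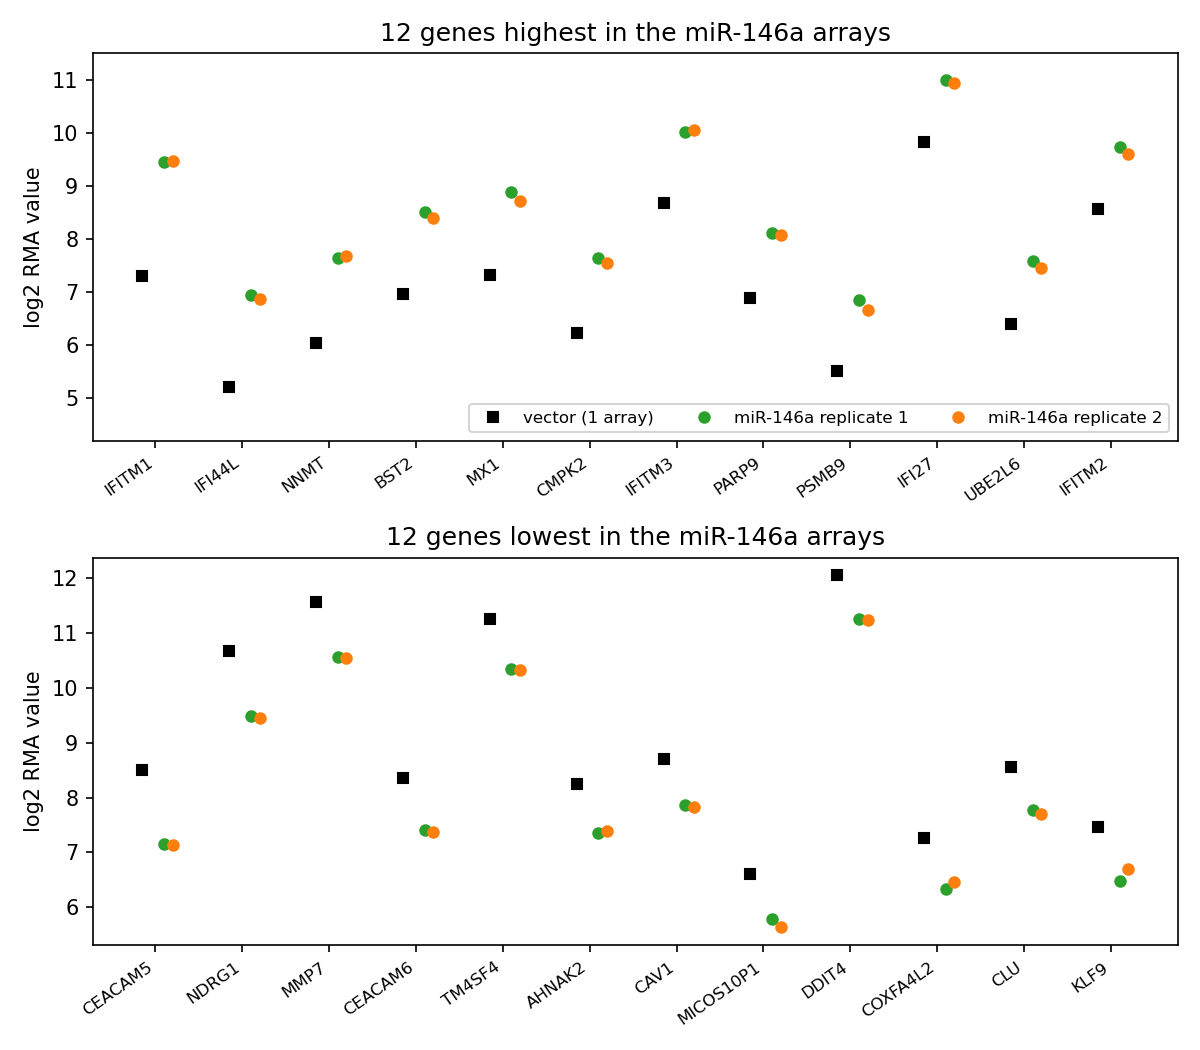
Log2 RMA value (y axis) in the vector array (black squares) and in miR-146a replicates 1 and 2 (green and orange circles) for the 12 genes highest (top) and 12 lowest (bottom) relative to the vector. The replicate SD is at most 0.15 for these genes, and every mean fold difference is at least 1.76.

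Genes of hypoxia and glycolysis were lower. Of 22 measured members, 19 were lower in both miR-146a arrays and 1, PFKFB3, was higher in both (mean log2 difference 0.08). Of the 37 genes at least 1.5-fold lower in both arrays, 1, NDRG1, belonged to this list, against 0.065 expected by chance. That count covers members of the fixed list only and does not say how many other hypoxia-responsive genes are among the 37. After NDRG1 the lowest were BNIP3L, a mitophagy receptor, at 1.49-fold lower, ADM, adrenomedullin, at 1.48-fold lower, and KDM3A, a hypoxia-induced histone demethylase, at 1.46-fold lower, while VEGFA (-0.29 on the log2 scale) and LDHA (-0.20) lay closer to the vector. This order holds for the probe set used per gene. The 4 probe sets of VEGFA above the filter ranged from -0.20 to -0.63 and the 3 of PDK1 from -0.27 to -0.92. The list median was -0.25 (-0.26 and -0.23 in replicates 1 and 2), below all 10000 matched random lists, whose central 95% ran from -0.04 to 0.08. No member passed limma over all genes and 8 passed adjusted over the list alone, all lower. With the prior from unequal replicates 8 passed over all genes and 12 adjusted over the list alone, all lower. Camera called the list lower with a preset correlation (adjusted p = 8.7e-08) and not otherwise (adjusted p = 0.83 with an estimated correlation). The lower 5′ signals of ACTB and GAPDH, by -0.18 to -0.32, were measured in the same arrays.

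Targets of Wnt and beta-catenin signalling were mostly higher. Of 17 measured members, 11 were higher in both arrays and 3 were lower in both, with a list median of 0.28 that lay above the central 95% of matched lists (-0.06 to 0.10), and that was 0.17 with each gene's probe sets averaged. ZNRF3, a ubiquitin ligase that limits Wnt receptors, was 1.53-fold higher, NKD1, an intracellular Wnt antagonist, 1.44-fold higher and MYC 1.37-fold higher, while MMP7 was lower as given above. AXIN2 (0.18 on the log2 scale) and LGR5 (0.09) lay closer to the vector. The 2 other probe sets of NKD1 differed by -0.02 and 0.00, and all averaged gave 0.17. Of these genes 6 passed limma adjusted over the list alone, 5 higher and 1 lower, and 0 over all genes. With the prior from unequal replicates 7 were higher and 1 lower. The camera call with a preset correlation (adjusted p = 0.0487) was lost (adjusted p = 0.83 with an estimated correlation).

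The reported targets of miR-146a, a list fixed beforehand from general knowledge of the microRNA, were not lower as a group. Of 22 measured members, 8 were higher and 4 lower in both arrays. The list median was 0.05, at percentile 82.5 of matched random lists, but 0.02 (percentile 61.0) with probe sets averaged and 0.01 (percentile 57.9) without replicate 1. IRAK1 had a log2 value of 12.10 ± 0.03 (SD, n = 2) against 12.11 in the vector, though its other probe set above the filter read lower by -0.34. TRAF6 read 7.23 ± 0.07 (SD, n = 2) against 7.29, and its other probe set was at -0.15. SMAD4 differed by -0.30 on the log2 scale with replicate values of -0.12 and -0.48, and its other probe sets ranged from -0.26 to 0.03. CXCR4, a chemokine receptor, was 1.62-fold higher (a log2 difference of 0.70, with a miR-146a SD of 0.04, n = 2), with other probe sets from 0.11 to 0.33. FADD was 1.34-fold higher, IRAK2 1.22-fold higher and EGFR 1.11-fold higher, with other probe sets of EGFR from -0.12 to 0.48. With all probe sets averaged the log2 differences were 0.38 for CXCR4, 0.13 for IRAK2 and 0.06 for EGFR. They were -0.18 for IRAK1, -0.10 for TRAF6 and -0.11 for SMAD4. NUMB was measured only through a probe set below the filter, at 3.69 in the vector and 3.37 ± 0.11 (SD, n = 2) in the miR-146a arrays. No member passed limma over all genes or adjusted over the list alone. With the prior from unequal replicates 2 members, CXCR4 and FADD, passed, both higher.

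Among inflammatory genes, 14 of the 21 measured NF-kB targets were higher in both arrays and 1, SOD2, was lower in both (-0.06 and -0.62 on the log2 scale). The neutrophil chemokines CXCL2 (1.72-fold), CXCL8 (1.52-fold) and CXCL3 (1.41-fold) were highest, and NFKBIA, the inhibitor of NF-kB, was 1.19-fold higher. With all probe sets averaged the log2 differences were smaller, at 0.31 for CXCL2, 0.31 for CXCL8 and 0.14 for NFKBIA. None of these genes had another probe set above the filter, so the averages take in probe sets below it. The list median of 0.13 lay at percentile 99.8 of matched lists, 3 members passed limma adjusted over the list alone and 0 over all genes, and the camera call (adjusted p = 0.0262) was lost (adjusted p = 0.83 with an estimated correlation). The Toll-like and interleukin-1 receptor signalling list had a median of -0.04 at percentile 4.0 (-0.01 at percentile 12.4 without replicate 1 and -0.01 at percentile 10.4 without the filter). Of its 17 members 5 were higher and 8 lower in both arrays. The most changed were IRAK2 at 0.29 (0.13 with its probe sets averaged), TAB2 at -0.19, MYD88 at 0.16 and TOLLIP at -0.13 (-0.05 averaged) on the log2 scale. The other probe set of TAB2 was at -0.59, and those of TOLLIP ranged from -0.19 to 0.18. In the MHC class I antigen presentation list 10 of 13 members were higher in both arrays and 1 was lower. Besides PSMB9, its highest members were PSMB8 (1.59-fold), TAP1, the peptide transporter subunit (1.42-fold), and HLA-B (1.30-fold, or 0.20 on the log2 scale with its probe sets averaged). Its median of 0.14 lay at percentile 99.6, 1 member passed limma adjusted over the list alone and 0 over all genes, and the camera call (adjusted p = 0.0487) was lost (adjusted p = 0.83 with an estimated correlation).

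Growth factor response genes were also higher. Of 20 measured members of the EGFR ligand and ERK response list, 15 were higher and 2 lower in both arrays, the median was 0.15 at percentile 99.9, 7 passed limma adjusted over the list alone, all higher, and 0 passed over all genes. FOSL1, an AP-1 subunit, was 1.52-fold higher, EPHA2 1.35-fold and DUSP4, a phosphatase induced by ERK, 1.27-fold, although the other probe sets of DUSP4 ranged from -0.06 to 0.45. Camera called this list (adjusted p = 0.0057) and lost it (adjusted p = 0.83 with an estimated correlation). Immediate early and heat shock genes did not go one way. FOSB and ATF3 (1.49-fold, with its other probe set above the filter at 0.11 and all averaged at 0.17 on the log2 scale) were higher, while the small heat shock protein HSPB1 (1.43-fold) and the co-chaperone DNAJB1 (1.41-fold) were lower. With a median of 0.08 the list lay at percentile 99.2, 8 members were higher and 3 lower in limma adjusted over the list alone, and 0 passed over all genes. Without the filter (0.01) or with a gene's probe sets averaged (0.04) this median lay inside the range of matched lists, and camera did not call the list (adjusted p = 0.717, or adjusted p = 0.838 with an estimated correlation). Of the 16 NRF2 list members measured, 10 were lower and 1 higher in both arrays, with a median of -0.07 at percentile 0.53. The 4 lowest members were the aldo-keto reductases AKR1B10 (1.61-fold), AKR1C2 (1.45-fold), AKR1C1 (1.44-fold) and AKR1C3 (1.37-fold), of which the last 3 are close paralogs, whereas NQO1 (-0.06 on the log2 scale) and GCLC (-0.01) lay near the vector. Of this list 3 passed limma adjusted over the list alone, all lower, and 0 over all genes, and camera called it (adjusted p = 0.0043) only with a preset correlation (adjusted p = 0.83 with an estimated correlation). Its median lay inside the range without the filter or without replicate 2.

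The epithelial list lay at the lower edge of the central 95% of matched random lists, just inside it here and outside with cyclic loess (percentile 2.215), and the mesenchymal list lay above it. In the epithelial list 15 of 25 measured members were lower and 5 higher in both arrays, with a median of -0.04 at percentile 2.70 (-0.02 at percentile 7.305 without replicate 1), and 0 passed limma over all genes or over the list alone. CDH17, an intestinal cadherin, was 1.46-fold lower and CLDN1 1.29-fold lower, CDH1 was at -0.09 on the log2 scale and CLDN4 was 1.19-fold higher (0.13 on the log2 scale with its probe sets averaged). Camera called the epithelial list lower (adjusted p = 0.0487) and lost it (adjusted p = 0.83 with an estimated correlation). The mesenchymal list had 7 of 12 members higher and 4 lower in both arrays and a median of 0.15 at percentile 99.7. TGFB2 was 1.94-fold higher and FN1 1.27-fold higher, but with all its probe sets averaged TGFB2 differed by 0.27 on the log2 scale, against 0.95. That list had 1 member higher and 1 lower in limma adjusted over the list alone and 0 over all genes, and without the filter on low signal its median of 0.00 lay at percentile 37.1. Camera did not call it (adjusted p = 0.589, or adjusted p = 0.83 with an estimated correlation).

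With the settings used here the remaining lists had medians inside the central 95% of matched random lists, and none had a member that passed limma over all genes. Outside that range under an alternative lay the enterocyte list with a gene's probe sets averaged (median -0.19, percentile 0.050), the stem cell list (percentile 99.9) and the unfolded protein response and ATF4 list (-0.05, percentile 0.985) without replicate 1, and the TGF-beta and BMP list without the filter (percentile 97.6). Adjusted over the list alone, limma passed 3 goblet cell genes as higher and 3 as lower, 1 unfolded protein response or ATF4 gene as higher and 3 as lower, and 1 stem cell marker each way. The medians were 0.05 for the Notch pathway (HES1 was 1.60-fold higher, or 0.41 on the log2 scale with its probe sets averaged), 0.09 for stem cell markers (PROM1 1.28-fold higher, ALDH1A1 1.18-fold lower), 0.09 for the TGF-beta and BMP response (CCN2 1.94-fold and PMEPA1 1.45-fold higher), 0.04 for the cell cycle (E2F1 1.37-fold higher, BUB1 1.25-fold lower) and 0.00 for p53 targets (AEN 1.46-fold higher). Medians were -0.03 for the unfolded protein response and ATF4 list (ASNS 1.56-fold lower), -0.01 for cholesterol synthesis (MSMO1 1.34-fold lower), 0.02 for enterocyte markers (CA2 1.58-fold lower, and -0.19 as above with probe sets averaged), -0.01 for goblet cell genes (TFF2 1.38-fold higher, REG4 1.33-fold lower), -0.03 for Paneth cell markers, 0.24 for enteroendocrine markers with only 2 members measured, and 0.11 for metallothioneins. Ribosomal protein genes had a median of -0.01 and commonly used reference genes 0.02. The stem cell median was -0.01 in replicate 1 and 0.18 in replicate 2, and -0.02 with probe sets averaged. The Notch median was 0.03 with probe sets averaged, 0.02 without the filter and 0.02 without replicate 1. Other medians turned sign, to 0.01 for cholesterol synthesis with probe sets averaged and 0.02 without replicate 2, to -0.01 for enterocyte markers without replicate 1 and for enteroendocrine markers without the filter, and to 0.00 for ribosomal protein genes with cyclic loess. The p53 median was 0.03 with probe sets averaged and -0.02 with cyclic loess, and the unfolded protein response and ATF4 median was -0.02 without replicate 2. Goblet cell genes stood at 0.00 without the filter, -0.02 with cyclic loess, -0.03 without replicate 1 and -0.02 without replicate 2, and Paneth cell markers at -0.01, -0.02 and -0.01 without the filter, replicate 1 and replicate 2. Reference genes stood at 0.00 with cyclic loess or without either replicate, ribosomal protein genes at 0.00 without replicate 2, cholesterol synthesis at 0.00 without replicate 1 and -0.02 with cyclic loess, and enterocyte markers at 0.01 with cyclic loess and 0.03 without replicate 2. For enterocyte markers and reference genes the median was above 0 while the mean (-0.06 and -0.02) and camera pointed down, and for p53 targets the median was 0.00 with a mean of -0.01 and camera pointing down.

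Most markers of other cells lay below the filter. ENG, an endothelial marker, was above it at 7.41 in both miR-146a arrays, 1.33-fold higher than in the vector (a log2 difference of 0.41, adjusted p = 0.118 in limma, 0.0156 with the prior from unequal replicates), but its other probe set differed by 0.00. COL1A1, a fibroblast collagen, read 7.33 in the vector and 7.17 in both miR-146a arrays, with its other probe set at 0.08. ENG and COL1A1 held exactly equal values in the miR-146a arrays, so their limma standard errors (0.0075 each) are those of tied genes. With the prior from unequal replicates these were 0.0855 each. Adjusted over the list alone, 1 endothelial member passed limma as higher and 1 fibroblast member as lower. The fibroblast list had 3 of 11 members above it with a median of -0.02, the leukocyte list 4 of 15 with a median of -0.06, the endothelial list 3 of 7 with a median of 0.13, and the packaging cell list 1 of 7 with a difference of -0.02. Without the filter the endothelial median was 0.02, the fibroblast median 0.00 and the packaging cell median 0.02. Without replicate 1 the fibroblast median was -0.06, the leukocyte median -0.01 (-0.12 with probe sets averaged) and the packaging cell value 0.00, and without replicate 2 the fibroblast median was 0.00 and the packaging cell value -0.04.

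**Figure D3:**
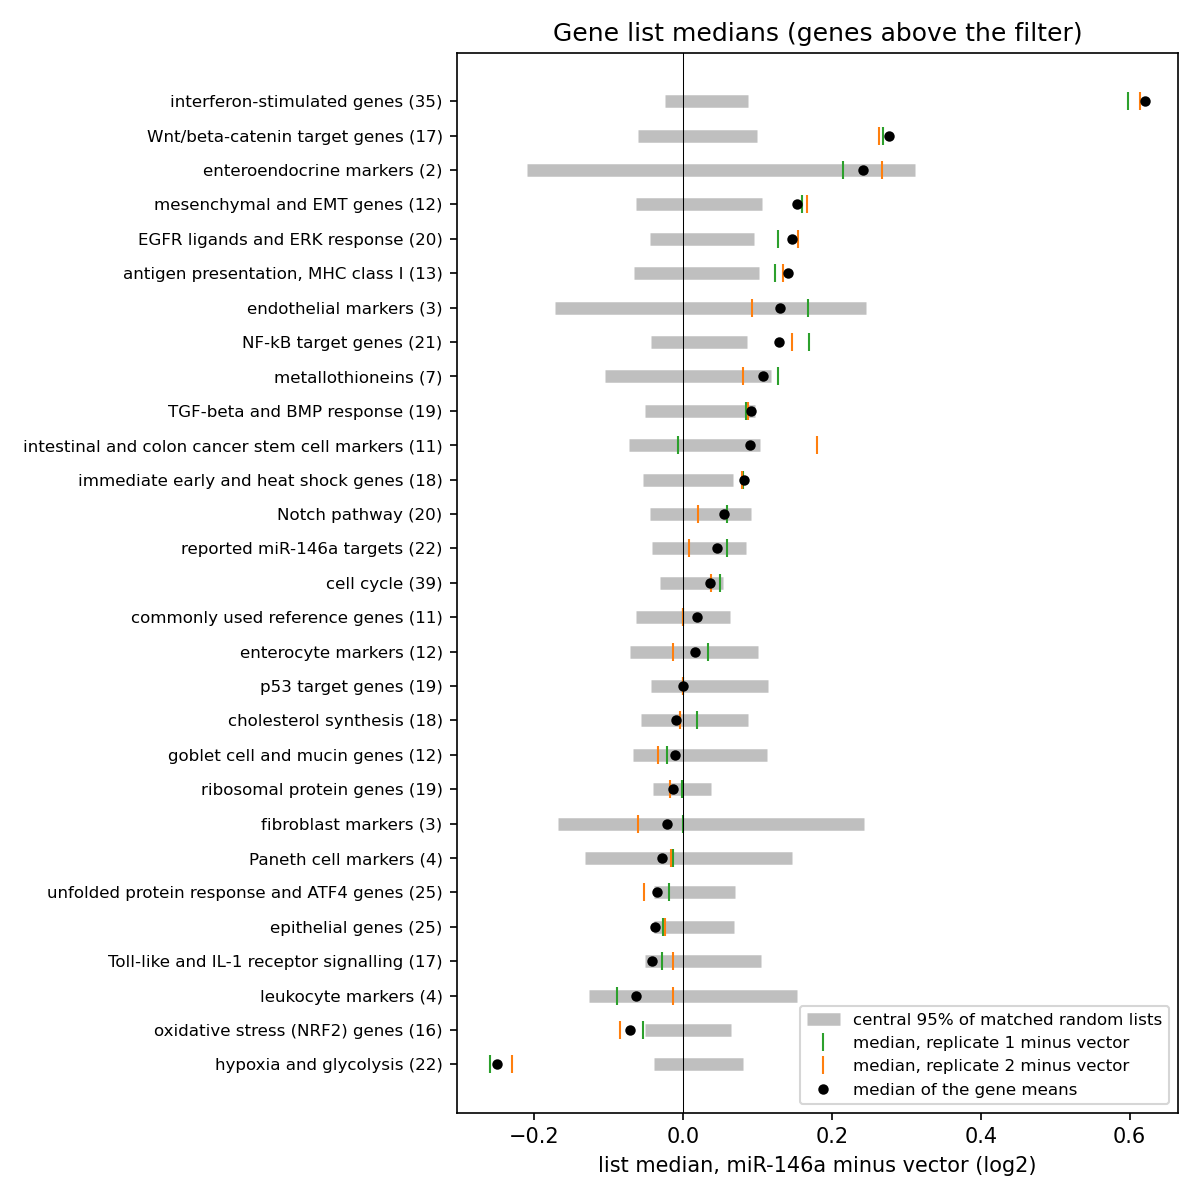
Median log2 difference between the miR-146a arrays and the vector array (x axis) for each gene list with at least 2 measured members (number in brackets), as the median of gene means (black), the medians of replicates 1 and 2 (green and orange) and the central 95% of 10000 random lists matched on mean expression (grey). The interferon-stimulated list stands at 0.62 and the hypoxia and glycolysis list at -0.25.

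Labelling controls differed between the groups. The 5′ probe set of ACTB was lower than in the vector by -0.29 and -0.18 on the log2 scale in the 2 miR-146a arrays and that of GAPDH by -0.32 and -0.30, whereas their 3′ probe sets differed by 0.05, 0.04, -0.03 and -0.02. The 5′ probe sets of the bacterial Dap, Lys, Phe and Thr transcripts, which are spiked into RNA before labelling, were lower in both miR-146a arrays, by -0.90 and -0.98 for Dap. Their 3′ probe sets were lower as well, by -0.31 and -0.31 for Dap and -0.38 and -0.65 for Lys. The 3′ minus 5′ difference of Dap was 2.34 in the vector array and 2.93 and 3.02 in the miR-146a arrays, whereas that of Lys was 1.79 against 1.63 and 1.73. Hybridisation controls, added after labelling, had a median difference of -0.09 over 9 probe sets. These shifts accompany every gene group above, because the vector group is a single array.

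**Figure D4:**
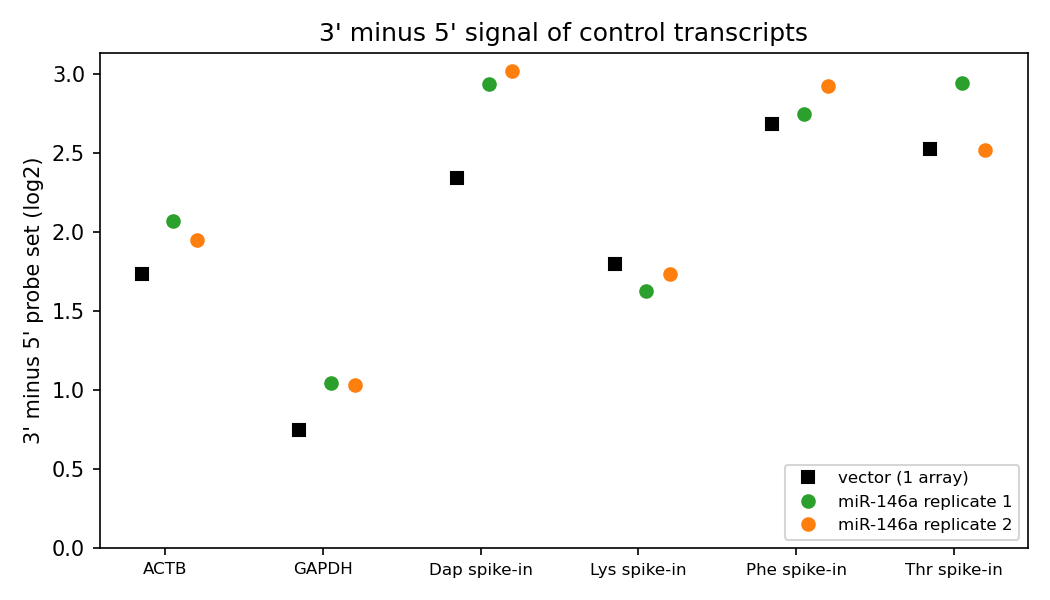
Difference between the 3′ and the 5′ probe set (y axis, log2) of 2 cellular and 4 spiked-in control transcripts in the vector array (black squares) and miR-146a replicates 1 and 2 (green and orange circles). ACTB stands at 1.73 in the vector and at 2.07 and 1.95 in the miR-146a arrays, and GAPDH at 0.75, 1.04 and 1.03.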

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

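The values in this part lie outside the main comparison and were chosen after they were seen. They are differences from the vector array in probe sets the gene comparison does not use. Apart from the 3′ probe set of 28S rRNA, the ribosomal RNA probe sets among the array's controls read higher in both miR-146a arrays than in the vector array. The mean log2 difference was 0.79 for the 3′ probe set of 18S rRNA, 0.72 for its 5′ probe set and 1.00 for the 5′ probe set of 28S rRNA, with replicate values of 1.10 and 0.91 for the last. The 28S middle probe set differed by 0.29 and the 3′ probe set by 0.02, with replicate values of 0.05 and 0.00 for the last. Among the 4726 probe sets above the filter that are not paired with a single gene here, 3 were at least 2-fold higher and 2 at least 2-fold lower in both miR-146a arrays, while at 1.5-fold 22 were higher and 51 lower.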

How the results depend on the processing

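The limma counts of 0 higher and 0 lower held under the 7 alternatives fixed beforehand that keep every array. They depended on the variance prior, in 3 settings chosen after the data were seen: with the prior from genes with unequal replicates 592 genes were higher and 294 lower, with those genes tested alone 517 and 278, and with a robust prior 433 and 202. In simulated data, ties alone took the calls from 94 to 0. The counts of 15 and 3 genes 2-fold apart in both arrays became 68 and 37 at 1.5-fold, and the lower count became 6 with every probe set counted. They ranged from 12 to 18 and stayed at 3 under the others, including without either miR-146a replicate, where 16 to 18 genes were higher. The 9 lists outside the central 95% of matched lists became 7 to 11 under the other settings, 8 by camera with a preset correlation and 0 with an estimated one, which rests on 1 residual degree of freedom. The interferon and hypoxia medians stayed outside under all 5 alternatives, between 0.58 and 0.62 and between -0.28 and -0.22. The mesenchymal list came inside without the filter (37.1th percentile), the NRF2 list without the filter or without miR-146a replicate 2 (at most 2.75), and the immediate early list without the filter or with mean probe sets. Lists inside the range that moved outside were the enterocyte list with mean probe sets (percentile 0.050), so that the 9 lists outside there are not the same 9, the epithelial list with cyclic loess (2.215), the stem cell (99.9) and unfolded protein response and ATF4 (0.985) lists without miR-146a replicate 1, and the TGF-beta and BMP list without the filter (97.6). The causes were not tested. Among the medians of the 9 lists under an alternative 26 moved by more than the SD between that list's medians in the 2 miR-146a arrays and 19 did not. Leaving out a replicate gives the same 2 medians that this SD is taken from. A main median lying between them mostly counts as not moved, so those settings say little about stability. For the 24 highest and lowest genes 10 values moved by more than the SD of that gene's 2 miR-146a values and 38 did not. None of these 2 sets changed sign, and the mesenchymal median was 0.00 without the filter. CEACAM5 was at -0.68 with all its probe sets averaged, NNMT at 1.04, CLU at -0.43 and KLF9 at -0.43. Leaving out a replicate allowed no limma test, and the single vector array could not be left out. No paired analysis was possible because the vector group has 1 array with no replicate number.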

Other observations

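The tests chosen only after the result was seen are those of the 5 added gene lists, of the 3 added limma settings (a prior from unequal replicates, those genes alone, a robust prior), of weaker labelling behind the lower hypoxia genes, of glucose-responsive genes, of the microRNA against other differences between cultures, and of the reported targets as an explanation. For the hypoxia genes the bound of the labelling test was extended to the upper quartile after its values were seen, which left open an explanation the earlier bound excluded. For the test of weaker labelling behind the higher interferon genes the bound was set first, but the reference and ribosomal medians in it had been seen.

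Another 5 groups were looked at only after the gene ranking was known, so their percentiles do not count as independent evidence. Histone genes were lower, with 6 of 7 measured members lower in both miR-146a arrays, a median log2 difference of -0.46 and a percentile of 0 among matched random lists. H2AC6 was 1.65-fold and H2BC21 1.49-fold lower, and many histone probe sets share sequence between copies of the family. Caveolar genes had a median of -0.21 (percentile 0.050), led by CAV1 and by CAV2, which was 1.63-fold lower, and the CEACAM family had a median of -0.12 (percentile 1.49) with 4 of 6 members lower in both arrays. YAP/TEAD targets had a median of 0.08 (percentile 89.0), although CCN2 and TGFB2 in that list were each 1.94-fold higher. Circadian clock genes had a median of 0.01 (percentile 34.985) and went both ways, with PER2 1.86-fold higher, PER3 1.44-fold higher and BMAL1 1.41-fold lower. With all probe sets averaged PER2 differed by 0.43, PER3 by 0.02 and TGFB2 by 0.27 on the log2 scale.

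For the higher interferon-stimulated genes, weaker 5′ labelling in the miR-146a arrays was predicted to split the probe sets of a gene. Of the 51 probe sets of this list 92.2% (47) were higher in both arrays, and the reference and ribosomal lists lay at 0.02 and -0.01. That share was above the bound set beforehand, but it includes the probe sets that showed the pattern. Only 14 of the 35 genes had several, so that share compares few probe sets within a gene and cannot decide the question. The direction is more telling: the 5′ probe sets of ACTB and GAPDH were lower, by -0.18 to -0.32 on the log2 scale. Of the 35 members 32 were higher and 2 lower in both arrays, with list medians of 0.60 and 0.61 in the replicates. These values argue against weaker 5′ labelling as the source of the higher values of this list. Some ribosomal RNA probe sets were higher in the same arrays, by 0.79 and 0.72 (18S 3′ and 5′) and 1.00 (28S 5′), more than the list median of 0.62, others less (0.29 and 0.02 for 28S middle and 3′), and an RNA or labelling difference of that kind was not tested and stays open. Treating each array in turn as the lone one, 1 of the 3 choices, the real one, gave a list median as large (0.62, highest other 0.33); 3 choices are too few for a share under 0.05. The bound set beforehand for the others was wrong by design, because each of them still holds the vector array on 1 side and carries part of the same difference. Whether the introduced microRNA or another difference between the transduced cultures lies behind it cannot be told apart with 1 vector array, and a different innate response to the lentiviral stocks may also contribute, untested here.

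The lower hypoxia and glycolysis genes were weighed the same way, and the test of weaker 5′ labelling was the last of 3 forms tried. The first took the list's 10 lowest genes, with 14 of 14 probe sets lower in both arrays, and was void because the genes were picked for the pattern; the next took all members, with 36 of 42 (85.7%) lower, against an arbitrary bound. In the last form, over the 11 list genes with several probe sets above the filter, the least lowered probe set of each had a median of -0.20. Its upper quartile of -0.09 and values near 0 for ENO1 (-0.02), ERO1A (-0.02) and SLC2A1 (-0.03) leave weaker labelling open. The 3′ spike-in signals were lower as well, but the 3′ probe sets of ACTB and GAPDH differed by 0.05, 0.04, -0.03 and -0.02, so the spike-ins do not decide it. The real choice of the lone array was the only 1 of 3 with a list median as large (0.25 in size, highest other 0.14), too few choices for a share under 0.05. A candidate explanation is a difference in oxygen or glucose supply between the dishes. TXNIP and ARRDC4, which respond to glucose and lie outside the list, had a mean difference of -0.73. Both genes were chosen after their values were seen, so this value is no independent evidence for a supply difference. With 1 vector array such a difference, the labelling and the microRNA cannot be told apart.

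Pairs of arrays held exactly equal values in 19.3% (the 2 miR-146a arrays), 16.9% and 18.6% (vector with replicates 1 and 2) of probe sets. A candidate explanation is the median polish of RMA: simulated probe sets of 11 probes gave an equal pair in at least 56.8% of cases with 3 arrays, about 23.6% at most with 5, 10.1% at most with 7 and 0% with 4. The observed shares lie below the simulated value for 3 arrays, so the number of arrays summarised together stays open. In simulated data such ties alone took limma's calls from 94 to 0.

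One hypothesis was that the introduced microRNA lowers its reported target transcripts as a group, and the values do not bear it out: the list median stood at the 82.5th percentile of matched lists, where under 2.5 was required, and at the 57.9th without miR-146a replicate 1. Effects on translation, or on targets chosen by seed sites, were not tested here.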
